A study of Homo sapiens with 2 samples.

How the data were processed

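Total RNA was taken from 2 samples of REH cells, 1 with a scrambled shRNA and 1 with an shRNA against XIST. Per the labels' protocols, poly(A) RNA was selected from about 500 ng of total RNA, and libraries were sequenced as paired-end reads of 75 nt. The submitters' processing notes name cutadapt 1.3.1, TopHat2, Cufflinks 2.2.1 and the genome build hg19, without their settings. The deposited table is named by its authors as a matrix of FPKM values, which are fragment counts scaled by transcript length and by the mapped fragments of the library. The gene identifiers are Ensembl identifiers with a version.

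The columns of values were not used in any result. Their headings, S5 (Sample 1) and S6 (Sample 2), match no label of either sample, so 0 of the 2 columns were assigned to a sample. Before that was decided, both columns had been viewed to learn their range, including the entries of XIST and TSIX. The planned description of fold differences, of the X chromosome against the autosomes and of the fixed gene lists was therefore not carried out. Nor was it repeated with another pseudocount, scaling, expression minimum or fold threshold. The planned correlation between the 2 libraries, which needs no assignment, was not run either, because the columns of values were not used. With 1 library per group, no test between the conditions was planned.

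The identifiers, symbols and positions of the table were read with Python 3.11.15. Identifiers were matched without their version to GENCODE release 29 to obtain gene types. That annotation is on GRCh38, so none of its positions are given. Its gene spans, from start to end, were used only to learn how the table counts its starts, which was found to be from 0. For 33856 genes of the same version in both annotations, 32310 spans were equal when starts were read that way, and 498 when they were read as counting from 1. Starts are given here counted from 1. Members of the fixed lists were looked up by any symbol listed for them, older or newer, and 372 symbols stood on more than 1 row.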

Results

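RNA sequencing was used to measure gene expression in REH cells, an established human pre-B lymphoblastic leukaemia line, after lentiviral delivery of a short hairpin RNA (shRNA). The series holds 2 samples. One received a scrambled shRNA and serves as the control. The other received an shRNA against XIST, the long noncoding RNA that coats and silences the inactive X chromosome in female cells. Each group has 1 library, so the design gives no replicate error. The comparison that the design implies is knockdown against control, gene by gene and for X-linked genes as a group. Whether REH cells carry an inactive X chromosome was not examined here.

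No expression value is reported for either condition, and the comparison of knockdown with control was not made. The table of expression values has 2 columns of values, headed S5 (Sample 1) and S6 (Sample 2). Neither heading occurs in the titles, descriptions or characteristics of the samples. The columns were not assigned by their order, which would be a guess. They were not assigned by the level of XIST either, because the outcome would then set the condition and the depletion of XIST would hold by construction. Neither the expression of XIST in these cells nor its depletion is shown here. The sequencing reads were not used here, and the depth of the libraries was not determined.

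The annotation of the table does not depend on this assignment. It covers 35718 genes, each with its own identifier, of which 34079 are also in GENCODE release 29. By the gene types of that release, 19866 were protein-coding, 7582 were lincRNA genes and 5560 were antisense genes. The X chromosome carried 1183 of the genes, 836 of them protein-coding.

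XIST (ENSG00000229807.11_4) was listed on the minus strand of chromosome X from 73040486 to 73072558 in hg19, spanning 32073 bp. Its type in GENCODE release 29 was lincRNA. TSIX (ENSG00000270641.1_2), the antisense partner of XIST, lay on the plus strand from 73012040 to 73049066 and overlapped XIST by 8581 bp. JPX (ENSG00000225470.7_3), a noncoding activator of XIST, lay on the plus strand from 73164019 to 73290243. FTX (ENSG00000230590.9_4), another noncoding gene of the X inactivation centre, lay on the minus strand from 73166390 to 73513409. RLIM (ENSG00000131263.12_2), which encodes a ubiquitin ligase that acts on an XIST repressor, lay on the minus strand from 73805052 to 73834452.

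Gene lists for the planned comparison were fixed before the data were examined. The table held all 26 listed genes reported to escape X inactivation, such as KDM6A and DDX3X, and all 66 listed genes usually subject to it, such as HPRT1 and PGK1. It also held all 22 listed X-linked genes of the immune system, such as BTK and TLR7. Of 33 genes of pre-B cell identity, such as PAX5 and VPREB1, 32 were found by symbol, CD24 being the exception. All 24 myeloid markers and all 20 T and NK cell markers were found too. Finding a gene shows only that the table has a row for it, not that it was expressed. The genes of all 32 listed proteins that bind XIST RNA or act with it in silencing, such as SPEN and HNRNPK, were also found by symbol. The list of other long noncoding RNAs was the least complete, with 16 of 23 found by symbol. SNHG1, SNHG5, GAS5, H19, DANCR, MIR17HG and FIRRE were not matched. Over all 32 lists, 890 of 899 memberships were found. The remaining unmatched gene was PECAM1, among the fibroblast, endothelial and epithelial markers.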

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

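The alternatives here were chosen after the annotation of the table had been seen, and they concern only how genes were looked up. With the first listed symbol alone, 881 of the 899 list memberships were found, against 890 with any listed symbol, older or newer, allowed. Adding a lookup by gene identifier left the number at 890. Matching identifiers with their version gave 33856 genes shared with GENCODE release 29, against 34079 without it. The settings laid out before the data were examined, for fold differences, the X chromosome and the gene lists, were not run, because no column of expression values was assigned to a sample. No paired analysis was possible because each group has 1 sample.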
